A study of Bos taurus with 15 samples.

How the data were processed

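The data are RNA-seq counts per gene from 15 libraries of bovine retinal endothelial cells in 2 experiments. Per the labels, RNA was extracted with a Qiagen RNeasy Plus micro kit and polyA RNA was made into libraries with an NEBNext Ultra II RNA kit. The deposited values are whole-number counts per gene, not normalized, in 1 table per experiment. Each table lists the same 27607 cattle Ensembl gene IDs in the same order, and all of its value columns were used. Per the submitters' processing notes, featureCounts and DESeq2 were used, with no versions. The same notes list the genome builds hg38 and ARS-UCD1.2 without saying what each was used for. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been assigned to either gene.

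The groups were control (4 libraries), succinylacetone (4), scrambled siRNA (4) and FLVCR2 siRNA (3), taken from the sample titles. The treatment labels of 2 of the 3 FLVCR2 siRNA libraries read siFLVCR3 and siFLVCR4, which as written name another target; their titles and the study's design text, which names FLVCR2 alone, were followed, and the level of FLVCR2 was not checked. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts of replicate pairs were compared by a chi-square statistic over genes with a summed count of at least 20. The statistic divided by its degrees of freedom lay between 3.75 and 46.9 (1 is sampling noise), so no pair differed by sampling noise alone, and every library counted as its own sample. The statistic cannot tell separate cultures from separate preparations of 1 culture.

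The files do not pair the gene IDs with names, and 0 IDs matched the reference gene table. The level of FLVCR2 itself, the 38 gene lists and 9 cell type marker lists fixed in advance, and the genes chosen in advance by symbol were therefore not analysed here. The rule fixed in advance for naming genes counts a gene without a symbol but does not name it. The 4 IDs printed lie outside that rule and were chosen after their values were seen. They are the largest rise in each comparison and the largest fall with FLVCR2 siRNA, among genes at adjusted p under 0.05, a mean CPM (the count scaled to a common library total) of at least 5 and no overlap between the groups. The remaining ID is the fall shared by both comparisons with the largest smaller fold change.

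Tests were run in R 4.3.3. Each treatment was compared with its own control alone with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust quasi-likelihood F test), with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Standard errors of log2 fold changes were the absolute fold change divided by the square root of F. CPM values were scaled by the TMM factors within each experiment. The difference of the effects was tested in 1 fit of all 15 libraries with 4 group means, as the contrast of the succinylacetone effect minus the siRNA effect. Shared calls were set beside the number that independent lists would share and beside 10000 random lists matched on mean expression in 20 bins, or on mean expression in 10 bins and the spread between replicates in 5 bins within each. The comparisons, the tests of genes, the correlation and most alternatives were fixed before the data were examined, and the matched lists and the tests against the control of the other experiment were added afterwards. The alternatives were DESeq2 1.42.0, RLE or upper-quartile factors, no filter beyond 1 count, a stricter filter (CPM of at least 1 in 3 libraries and mean CPM of at least 5), limma 3.58.1 voom with quality weights, all 15 libraries in 1 fit, the replicate number as a block, each library left out in turn, and stricter thresholds.

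Totals lay between 18842196 and 34754170 counts per library, and the biological coefficient of variation was 0.0658 in the succinylacetone experiment and 0.0733 in the siRNA experiment. The tests were checked on simulated counts with the real means and library sizes. For succinylacetone, with 12727 genes, 56.7% of genes changed 1.25-fold were called, 86.6% at 1.5-fold and 95.5% at 2-fold. For FLVCR2 siRNA, with 12976 genes, these shares were 46.3%, 82.1% and 90.9%. For the difference of the effects, with 13193 genes, they were 11.9%, 58.2% and 74.2%. Of the unchanged simulated genes, 9 of 12527, 4 of 12776 and 6 of 12993 were called. The simulations changed 66 or 67 genes at each fold, a far smaller share than the 29.4% called with succinylacetone. Recovery and false calls depend on that share, so these rates do not carry over to the succinylacetone comparison. Figures were drawn with matplotlib 3.10.9.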

Results

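PolyA RNA of bovine retinal endothelial cells, the cells that line the blood vessels of the retina, was sequenced in 2 experiments. In the first, 4 libraries of cells treated with succinylacetone, an inhibitor of the heme synthesis enzyme aminolevulinate dehydratase, were set against 4 control libraries. In the second, 3 libraries of cells given an siRNA against the membrane transporter FLVCR2 were set against 4 libraries of cells given a scrambled siRNA. The treatment labels of 2 of these 3 libraries read siFLVCR3 and siFLVCR4, while their titles abbreviate the target as siF with a number. They were placed in the FLVCR2 siRNA group because the study's design text names FLVCR2 alone. By its title, the study asks how FLVCR2 acts on heme inside cells and on vessel growth in the retina. The control libraries held 28449599, 21901561, 25987785 and 21228468 counts in replicates 1 to 4, and the succinylacetone libraries 31736292, 18842196, 26912274 and 25377270. The scrambled siRNA libraries held 19031911, 23553784, 21065285 and 29297141 counts, and the 3 FLVCR2 siRNA libraries 34754170, 28097335 and 27927005. Between 14608 and 15625 of the 27607 genes had at least 1 count in a library. The tables name genes by Ensembl ID and do not pair the IDs with gene names, so the level of FLVCR2 and of other genes known by name was not analysed here.

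Succinylacetone changed the level of many genes by small amounts. Of 12727 genes tested, 1718 rose and 2018 fell, in all 3736 or 29.4%, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The median change of these genes was 1.22-fold (log2 0.28). At least 1.5-fold changes were fewer and were more often falls: 172 genes rose and 355 fell by that much, and 55 rose and 106 fell by at least 2-fold. Called rises above 2.003-fold were all in genes with a mean under 5 CPM or with overlap between treated and control libraries. Outside such genes the largest fall was 4.86-fold. In 1329 of the genes that rose and 1687 of those that fell, no treated library overlapped a control library. Over all genes tested, 27.8% were separated in this way, against 2.86% by chance for 4 libraries against 4. Calls came from low and high levels of expression. With the genes in 4 equal bins of mean expression, 196 rose and 241 fell in the lowest bin, up to 6.40 CPM, and 622 rose and 771 fell in the highest, from 63.6 CPM. The first principal component held 38.4% of the variance and separated the treated from the control libraries.

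The largest rise among separated genes with a mean of at least 5 CPM was in ENSBTAG00000005104. Its mean rose from 4.29 ± 0.530 to 8.66 ± 1.001 CPM (SD, n = 4 each), a log2 fold change of 1.002 (SE 0.136, edgeR adjusted p = 1.14e-06), and every treated library lay above every control library. The largest fall in the same set was larger than any rise: the gene's mean went from 50.04 ± 4.12 to 10.3 ± 2.19 CPM (SD, n = 4 each), a log2 fold change of -2.28 (SE 0.110, edgeR adjusted p = 4.31e-11). ENSBTAG00000017280 fell from 88.7 ± 4.19 to 45.7 ± 1.89 CPM with succinylacetone (SD, n = 4 each), a log2 fold change of -0.95 (SE 0.0515, edgeR adjusted p = 7.12e-15).

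**Figure D1:**
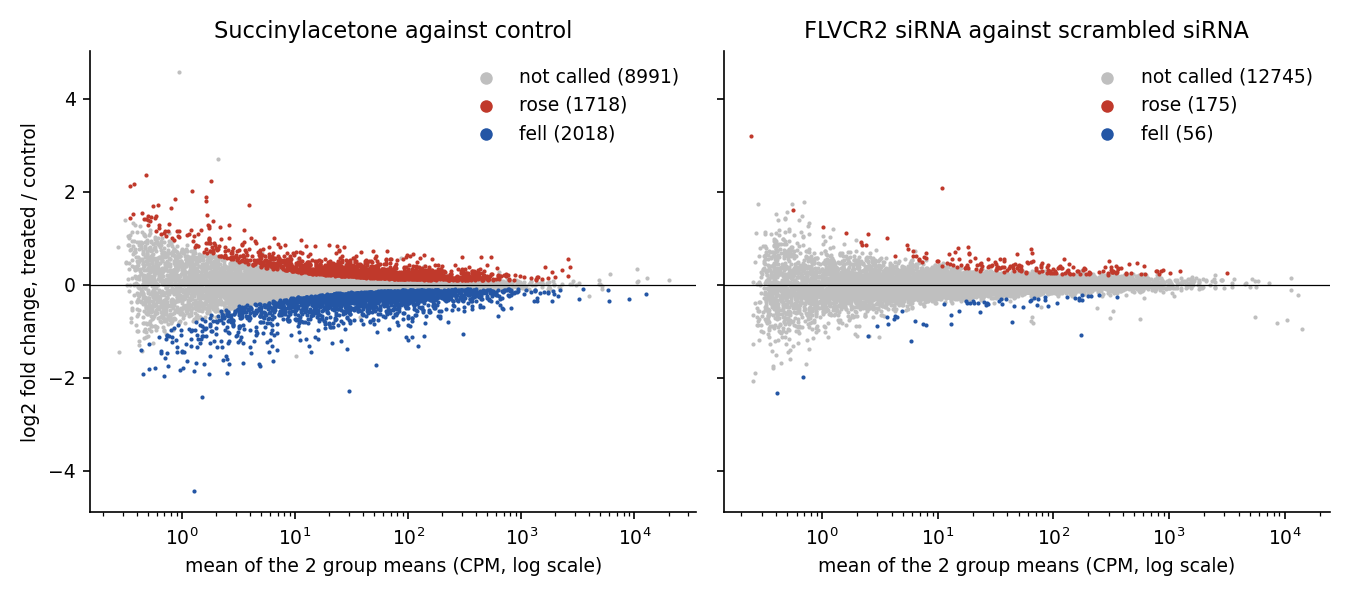
Log2 fold change of each tested gene (treated over control, vertical axis) against the mean of its 2 group means in CPM (horizontal axis, log scale), for succinylacetone (left) and FLVCR2 siRNA (right). Red points rose and blue points fell at an edgeR adjusted p under 0.05 (1718 and 2018 genes on the left, 175 and 56 on the right), and grey points were not called.

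FLVCR2 siRNA changed fewer genes, and most of these rose. Of 12976 genes tested, 175 rose and 56 fell relative to scrambled siRNA, in all 231 or 1.78%, by the same test and threshold, and 75.8% of the calls were rises. At an unadjusted p under 0.05 the share was lower, 59.0%, with 917 genes higher and 637 lower. The median change of the called genes was 1.30-fold (log2 0.38). At least 1.5-fold changes were found for 27 genes that rose and 18 that fell, and at least 2-fold changes for 7 and 5. The groups were separated in 173 of the genes that rose and in all 56 that fell. Over all genes tested, 12.1% were separated, against 5.71% by chance for 4 libraries against 3. In the highest of 4 equal bins of mean expression, from 63.4 CPM, 81 genes rose and 20 fell, and in the lowest, up to 5.84 CPM, 12 rose and 10 fell. The number of calls depended on single libraries and on the model: it was 84 without FLVCR2 siRNA replicate 2 and 150 without scrambled siRNA replicate 3, and 385 with no low-count filter, 391 with all 15 libraries in 1 fit and 471 with limma-voom. A set of 6 abundant IDs that varied between libraries of the same group took 1.71% ± 0.171 of the counts with FLVCR2 siRNA (SD, n = 3) and 3.11% ± 0.990 with scrambled siRNA (SD, n = 4), with a two-sided exact permutation p of 0.0857.

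The largest rise with FLVCR2 siRNA was in ENSBTAG00000005260, from 4.15 ± 0.486 CPM (SD, n = 4) to 17.4 ± 1.75 CPM (SD, n = 3), a log2 fold change of 2.07 (SE 0.118, edgeR adjusted p = 7.66e-11). The same gene rose with succinylacetone, from 19.5 ± 1.32 to 34.1 ± 2.66 CPM (SD, n = 4 each), a log2 fold change of 0.81 (SE 0.0746, edgeR adjusted p = 7.09e-10). As a fold change, though not in CPM, the rise was larger with the siRNA (edgeR adjusted p of the difference of log2 fold changes = 6.67e-09). Scaled within each experiment, the scrambled siRNA mean of this gene lay well below the 19.5 CPM of control and the FLVCR2 siRNA mean near it. Control belongs to the other experiment, so this gap cannot be told apart from a difference between the experiments. The largest fall with FLVCR2 siRNA was in ENSBTAG00000005108, from 8.22 ± 0.454 CPM (SD, n = 4) to 3.53 ± 0.318 CPM (SD, n = 3), a log2 fold change of -1.22 (SE 0.132, edgeR adjusted p = 7.67e-06). Its mean in control was 5.21 CPM, between those of the siRNA groups. With succinylacetone its log2 fold change was 0.30 (edgeR adjusted p = 0.108), and the effects differed (edgeR adjusted p = 1.67e-07). ENSBTAG00000017280, which fell with succinylacetone, also fell with FLVCR2 siRNA, from 55.7 ± 2.42 CPM (SD, n = 4) to 32.1 ± 1.78 CPM (SD, n = 3), a log2 fold change of -0.80 (SE 0.0712, edgeR adjusted p = 3.85e-07). A difference between its falls was not detected (log2 difference -0.15, edgeR adjusted p = 0.225). Its mean in control, 88.7 CPM, lay above those of both siRNA groups, and the FLVCR2 siRNA mean was the farther from it. ENSBTAG00000005104, which rose with succinylacetone, had a log2 fold change of -0.49 with FLVCR2 siRNA that missed the threshold (edgeR adjusted p = 0.0644). The same change passed it under DESeq2 (adjusted p = 0.0476), with no low-count filter (0.0393), with all 15 libraries in 1 fit (0.0444) and with the replicate number as a block (0.0355). The adjusted p ran from 0.0355 to 0.249 over the alternatives. The effects on this gene differed (edgeR adjusted p = 2.03e-07). Its mean was 6.99 CPM with scrambled siRNA and 4.98 CPM with FLVCR2 siRNA, the nearer of them to the 4.29 CPM of control.

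**Figure D2:**
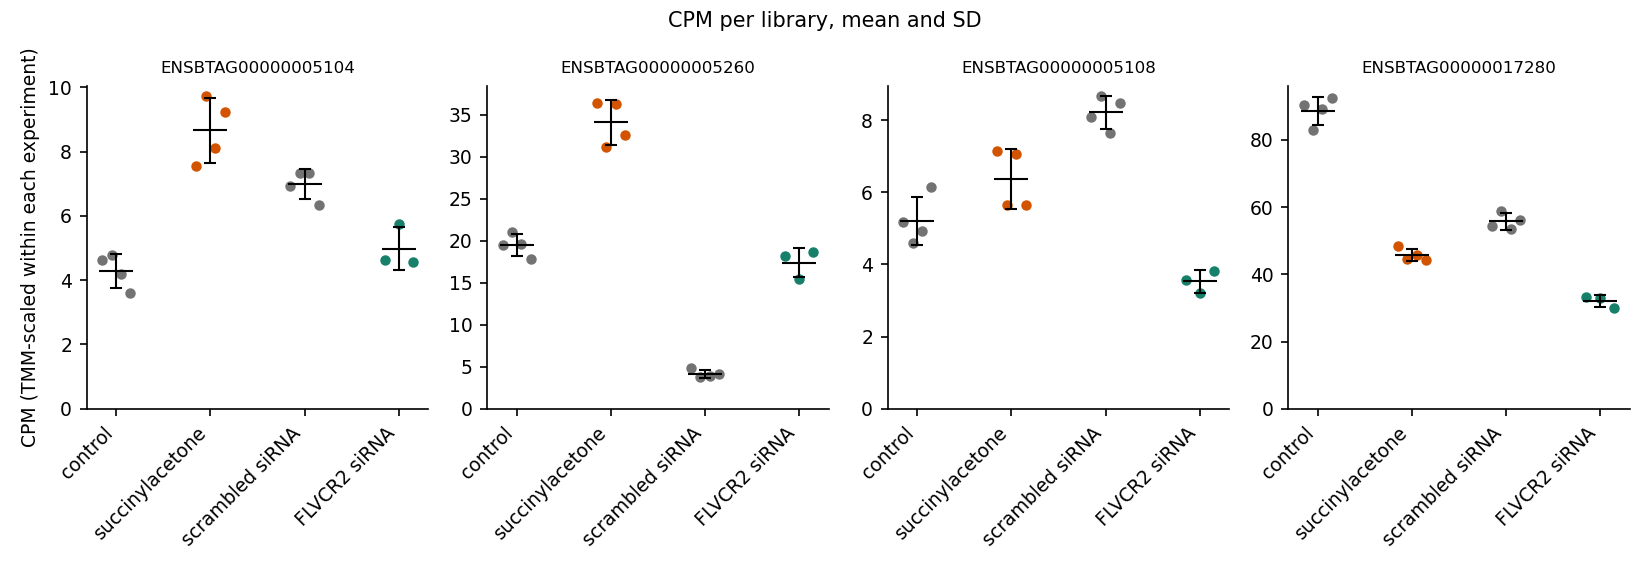
CPM of 4 gene IDs in each library (points), with the mean and SD of each group (black), scaled within each experiment. ENSBTAG00000005260 lies at 17.4 CPM on average with FLVCR2 siRNA against 4.15 CPM with scrambled siRNA, and ENSBTAG00000017280 is lower in both treated groups than in their controls.

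The responses to succinylacetone and to FLVCR2 siRNA were then compared, since by the study's title and design both bear on heme in the same kind of cell. Over the 12667 genes tested in both, the log2 fold changes showed little relation across genes, which are not independent replicates (Pearson r = -0.0363, Spearman rho = -0.0799). Errors in the fold changes weaken such a correlation and were not corrected for, so these values do not show that the responses are unrelated. Over genes called with FLVCR2 siRNA the values were 0.0935 and 0.121, and over genes called in both 0.153 and 0.0905. Both comparisons called 122 genes. Of these, 52 moved in the same direction (42.6%) and 70 in opposite directions. The number shared depended on single libraries and on the model: it was 48 (21 and 27) without FLVCR2 siRNA replicate 2, 82 (39 and 43) without scrambled siRNA replicate 3 and 229 (105 and 124) with limma-voom. The 122 genes made up 53.3% of the 229 genes called with FLVCR2 siRNA, where succinylacetone changed 29.5% of all genes, and lists matched on expression and on the spread between replicates shared 80.4 genes on average (95% of draws 67 to 94). These draws, like those that follow, treat genes as independent, so their ranges are too narrow where genes move together. The most frequent pairing was a fall with succinylacetone and a rise with FLVCR2 siRNA, in 57 genes. Independent lists would share 27.7 genes in this pairing, and lists matched on expression shared 34.6 on average (95% of draws 25 to 45). In 18 genes both treatments gave a fall, also above the 9.62 (4 to 15) of lists matched on expression. The other pairings lay within the matched range: 34 genes rose in both, against 28.7 (20 to 38), and 13 rose with succinylacetone and fell with FLVCR2 siRNA, against 7.99 (3 to 13).

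**Figure D3:**
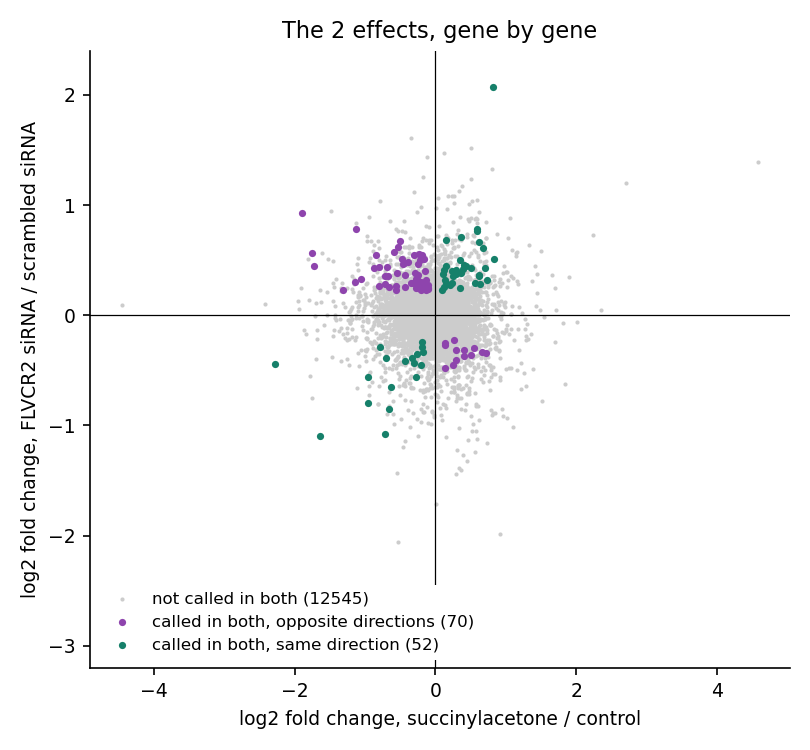
Log2 fold change with FLVCR2 siRNA (over scrambled siRNA, vertical axis) against that with succinylacetone (over control, horizontal axis), 1 point per gene tested in both. Green points are the 52 genes called in both in the same direction, purple points the 70 called in opposite directions, and grey points the other 12545 genes.

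The effects themselves were tested against each other in a fit of all 15 libraries. Of 13193 genes, 2190 differed at an edgeR adjusted p under 0.05, with the succinylacetone effect the higher in 850 and the lower in 1340. Of the 52 genes called in the same direction, 13 passed this test. Of the 229 genes called with FLVCR2 siRNA and tested in both, 155 passed it, among them all 70 called in opposite directions. These genes were chosen on effects that enter the contrast, so their passing is not independent evidence of a difference. The called genes were also compared between the control groups, although they were chosen on the same scrambled libraries. In a joint scaling of all libraries, 153 of the 174 genes that rose with FLVCR2 siRNA and 8 of the 55 that fell had a lower mean log2 CPM with scrambled siRNA than in the control of the succinylacetone experiment, as did 47.4% of the 12667 genes. With 2 scrambled libraries used for the calls and the other 2 for the difference from control, 79.5% of called genes and 57.6% of all genes moved against that difference, on average over 6 divisions of the libraries (73.4% to 85.3% for called genes).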

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

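Control replicate 1 lay farther from the other libraries of its group than those lay from one another. Its root mean square difference in log2 CPM to the other control libraries averaged 0.367, against 0.322 to 0.324 for the other 3. It also stood apart on the second principal component of that experiment (15.3% of the variance), at 24.5 where the other control libraries lay between -13.0 and -6.41. Without it, succinylacetone gave 3658 called genes (1644 rose and 2014 fell), of which 3259 were among the 3736 called with it. Chance alone marks about 1 in 20 groups in this way, and it was the only mark among 27 sets of 4 values tested.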

How the results depend on the processing

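Thinning and leaving out the 6 abundant IDs were chosen after seeing the data, as were, for the difference and the correlation, upper-quartile factors, no low-count filter and limma-voom, for the difference both stricter thresholds, and for the correlation 1 fit of all libraries. The number of genes changed by succinylacetone stayed between 2987 and 3954 in 18 of 20 alternatives, and was 2397 at an adjusted p under 0.01 and 161 with a 2-fold minimum. The number changed by FLVCR2 siRNA was 385 with no low-count filter, 471 with limma-voom, 391 with all 15 libraries in 1 fit, 108 at an adjusted p under 0.01 and 12 with a 2-fold minimum, and between 84 and 217 with 1 library left out. Stricter thresholds lower counts by construction, and the cause of the other shifts was not tested. With the 2-fold minimum 58.3% of the siRNA calls and 34.2% of the succinylacetone calls were rises. The number of genes whose effects differed was 1227 at an adjusted p under 0.01, 200 with a 2-fold minimum, and between 1652 and 2805 in the other 24 alternatives. The correlation of the effects was -0.0875 under the stricter filter, and -0.0873 with the reported fold changes over genes with a mean of at least 5 CPM in both, so that leaving out low genes gave the shift; it was between -0.0683 and 0.0113 in the other alternatives. For the 4 printed IDs, the 9 called values (effects and differences) kept their direction and passed the threshold in all 177 alternative values. The 3 uncalled ones kept their direction in all 59 and passed it in 4, all for ENSBTAG00000005104 with siRNA, the replicate block among them. The replicate block gave 3837 genes for succinylacetone, 277 for FLVCR2 siRNA (190 of them also called without the block), 2130 for the difference and a correlation of -0.0262. The labels do not say whether same-numbered libraries were handled together. Their deviations correlated at -0.0154 to 0.0569 with succinylacetone and -0.00321 to 0.0382 with siRNA, and 1 of 4 and 0 of 3 treated libraries correlated best with their own number. With so few pairs these values cannot exclude a pairing. Alternatives for the FLVCR2 level and for gene lists were not run. Depth and spread limit small changes: of the smallest changes simulated, 46.3% were called in the siRNA experiment.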

Other observations

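The shared calls with 1 library left out, the succinylacetone calls made on 2 of the control libraries, the thinning of libraries and the removal of the abundant IDs were chosen after the result was seen. The tests against the control of the other experiment were added after the data were examined, before their own values were known; the margin of 1 standard error in reading them, and the rule that a scaling must move the median log2 fold change by 0.01 to count, were set afterwards.

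For each treatment the real split gave more called genes than any other, while for the correlation many splits gave as large a value. Every other split mixes treated with control libraries, which widens the spread within groups, so few calls could come from it. The smallest share that 35 splits can give is 1 in 35. Of the 35 splits of the succinylacetone experiment, 1 gave as many as 3736 called genes, the real one, and the highest of the others gave 0. Of the 35 splits of the siRNA experiment, 1 gave as many as 231, the real one, and the highest of the others gave 23. For the genes whose effects differ, 1 of 100 relabelled sets gave as many as 2190. The highest of the others gave 2068. It was among 5 sets that kept the succinylacetone libraries apart from the control libraries, some of them with these labels exchanged. These sets gave 1104 to 2068, while the remaining sets gave at most 41. With the succinylacetone labels exchanged and the siRNA groups in place, 1735 genes were called. The count of genes whose effects differ thus depended on the succinylacetone effect. Relabelling did not test whether the effects are equal, so chance on the siRNA side of this count is not excluded. For the correlation of the effects, 18 of 35 splits of the succinylacetone experiment gave an absolute value as large as the observed one, and the highest of the others was 0.108, so that chance could account for it.

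The excess of rises among the genes changed by FLVCR2 siRNA was not accounted for by depth or a single library in the tests run. The excess was smaller over a wider set of genes: 59.0% were higher at an unadjusted p under 0.05, and 742 against 581 remained without the called genes. With all libraries thinned to the smallest total, 78.8% of the calls were rises, against 75.8% as deposited, and leaving out each library in turn gave at least 70.1%. Under DESeq2, RLE or upper-quartile factors, or without the abundant IDs, the lowest share was 74.3%, but these left the median log2 fold change over all genes between -0.00984 and -0.00422, close to the -0.00711 as reported, so that an effect of scaling cannot be told apart. A response to the loss of FLVCR2, an effect of the siRNA on other targets and a shift caused by the scrambled siRNA, taken up below, may each give such an excess. All of them stay open beside scaling.

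The calls that both comparisons shared outnumbered those of matched lists and went in mixed directions, with 40.6% to 48.2% moving the same way over the alternatives. The matched lists treat genes as independent, so their ranges are too narrow where genes move together, and the overlap was not tested by regrouping libraries. By this measure genes with little spread between replicates are not the whole source, since lists matched on expression and spread shared 80.4 genes on average and 94 at the upper end of the 95% range, against 122 observed. The number itself moved with single libraries, to 48 without FLVCR2 siRNA replicate 2 (29.1 in matched lists, upper end 37) and 82 without scrambled siRNA replicate 3 (51.8, upper end 63), and it lay above the matched range without each of the 15 libraries in turn. A candidate explanation for the opposite pairings is that scrambled siRNA differed from control as succinylacetone did: with 2 control libraries for the calls and the other 2 for the difference of scrambled siRNA from control, the sign was shared by 63.4% of the genes called with succinylacetone (59.1% to 65.6% over 6 divisions) and, with the controls divided alike, by 56.5% of all genes. For the genes called in both comparisons on all libraries it was shared by 86.2% of those with opposite directions and 17.6% of those with the same direction, values that the choice of these genes by both effects can set, so for them the explanation stays open.

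Genes called with FLVCR2 siRNA tended to move against the difference between scrambled siRNA and the control of the other experiment. Of the 174 that rose and were tested in both experiments, 153 (87.9%) had a lower mean with scrambled siRNA than in control, as did 8 of the 55 that fell (14.5%) and 47.4% of all genes. Chance values of single scrambled libraries, which enter both differences, do not account for all of it. With 2 scrambled libraries for the calls and the other 2 for the difference from control, 79.5% of called genes still ran against it on average (73.4% to 85.3% over 6 overlapping divisions), against 57.6% of all genes. A chance deviation shared by all scrambled libraries stays in both parts, so the division cannot exclude it. The mean with FLVCR2 siRNA lay closer to control than that with scrambled siRNA for 70.3% of the called genes and 56.2% of all genes, past a bound of 70% set beforehand by less than its binomial standard error. This share used the same scrambled libraries as the calls, which can raise it, and it was not repeated with divided libraries. By the divided libraries, a shift caused by the scrambled siRNA may be part of these calls. It cannot be told apart from a difference between the experiments, since the siRNA experiment held no library without siRNA.

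The 6 abundant IDs (mean of at least 100 CPM and a within-group SD of at least 0.4 in log2 CPM) varied together within groups, with a median pairwise correlation of 0.875 (0.463 to 0.982) of their deviations over the 15 libraries. Their share of the counts ran from 2.05% to 5.13% in control libraries, 1.88% to 5.16% with succinylacetone, 1.90% to 4.09% with scrambled siRNA and 1.57% to 1.90% with FLVCR2 siRNA. Control and succinylacetone libraries did not differ detectably in this share (two-sided exact permutation p = 0.886). Within groups the share tended to be smaller in libraries with larger totals (Pearson r = -0.523, Spearman rho = -0.386). The permutation p was 0.0479 for r and 0.157 for rho, and 0.0958 and 0.157 after Benjamini-Hochberg adjustment, so a relation to depth is left open. Without these IDs, FLVCR2 siRNA gave 250 called genes (192 rose and 58 fell), among them all 231 called with them.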
